A study of Mus musculus with 6 samples.

How the data were processed

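MicroRNAs were measured by small-RNA sequencing in a cultured mouse epicardial cell line. Epicardial cells form the outer layer of the heart. Per the labels, the cells received either an empty-vector lentivirus (EV, 3 libraries) or a lentivirus for CRISPR/Cas9 knockout of the histone deacetylase gene Hdac3 (KO, 3 libraries). Per the labels' protocols, RNA was extracted with Trizol, small-RNA libraries were built with a NEBNext kit by ligating adaptors to both ends of each small RNA, and the amplified products were size-selected on a gel. Ligation and size selection favour some microRNAs over others, so levels are best compared for 1 microRNA between libraries. The libraries hold no molecular identifiers that the labels mention, and PCR copies were therefore counted as reads.

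The deposited count table gives the authors' whole-number read counts for 1028 mature microRNAs in the 6 libraries, of which 17 are predicted microRNAs without a miRBase name. Per the submitters' processing notes, Bowtie, the mm10 mouse genome build and DESeq 1.8.3 were used, and the series' design text names DESeq2 with an adjusted p threshold of 0.05. How reads that match several microRNAs were counted, and which miRBase release was used, is not given in the sources used here. The deposited TPM values equal each count scaled to a library total of 1000000, to within 3.49e-10, so they contain no length term and were not tested. The authors' deposited comparison table lists 78 microRNAs with a mean normalized count per group (a signal with no spread), a log2 fold change, a p-value and an adjusted p-value. Its group means equal the deposited counts divided by median-of-ratios size factors.

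The libraries held 11824881 to 13412774 counts, and 1 read corresponded to between 0.0637 and 0.0892 CPM. CPM here are counts per 1000000 of the library total times its TMM factor. The factors were 1.23, 1.04 and 0.919 for EV 1, EV 2 and EV 3, and 0.920, 0.986 and 0.945 for KO 1, KO 2 and KO 3. No pair of libraries of a group agreed within counting noise, as 1 library deposited again would, the closest pair, KO 1 and KO 3, giving a chi-square of 9064 on 457 degrees of freedom. This does not show that they were separate cultures. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

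KO was compared with EV by edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15), the quasi-likelihood F test, which is two-sided, and Benjamini-Hochberg adjustment at 0.05. A microRNA that passed is described as called, or as having risen or fallen. The filter left 460 microRNAs, 2 of them predicted. Standard errors and 95% intervals refer to log2 fold changes of KO over EV. The 20 microRNA lists were tested with camera (limma 3.58.1) on voom values where at least 3 members were tested, which left 18, at a preset correlation of 0.01 and again with a correlation estimated for each list. Arms of 1 hairpin and neighbours in 1 cluster count as separate members, although they are not independent. List counts and list p-values may overstate the evidence for that reason. Differences within genomic clusters, and between the arms of a hairpin, were tested with limma's diffSplice on voom values. Clusters joined single-locus microRNAs on 1 strand with gaps of at most 10000 bp and at least 3 tested members.

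The test, the lists and the rule for named microRNAs were fixed before the data were examined. The miR-322/miR-503 cluster was listed because it was the candidate already known for this study. Its list results are therefore not independent support. The rule names every tested member of the X-linked miR-322/miR-503 cluster and the 5 most abundant microRNAs. It also names the 8 largest rises and the 8 largest falls among called microRNAs with non-overlapping groups and a mean of at least 10 CPM. For each other list it names up to 3 called members with the smallest adjusted p, or the most abundant member where none was called. The lists were the miR-322/miR-503 cluster, the miR-15/16 seed family, let-7, the miR-17-92 clusters, miR-34/miR-449, miR-200, mesenchymal, miR-29, muscle, endothelial and blood-cell microRNAs, a neural, liver and pancreas list, the Dlk1-Dio3 and Sfmbt2 clusters, pluripotency microRNAs, miR-23/27/24, miR-221/miR-222, miR-181, Hox-cluster and Igf2/H19 microRNAs.

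The alternatives fixed beforehand were median-of-ratios factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 10 CPM in 3 libraries, leaving out the 5 most abundant microRNAs, known microRNAs only, a replicate block, a minimum of 2-fold, an estimated list correlation, and each library left out in turn. Added after the data were seen were 1 surrogate variable (sva 3.50.0), leaving out EV 3 and KO 2 together, DESeq2 with a local dispersion trend, 1 member per pair with near-equal counts, and library sizes without miR-21a-5p. In 12 pairs of microRNA names the counts lay within 2% or 2 reads in every library, which points to shared reads, and changes in such pairs are uncertain. Hairpin positions are from GENCODE M21 (GRCm38, the same build as mm10), which held at least 1 locus for 929 of the 1011 known names.

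The tests were checked on simulated counts for KO against EV. Of 448 tested microRNAs, edgeR called 28.6% of the 49 changed 1.3-fold, 56.2% of the 48 changed 1.5-fold and 86% of the 50 changed 2-fold. A further 47 were changed 4-fold, and 1.57% of those left unchanged were called. The share changed was thus larger than the share called in the data, 35 of 460. Benjamini-Hochberg adjustment is less strict where many microRNAs change. The recovered shares may therefore be too high for the comparison of KO with EV. With 1 arm of a hairpin moved 2-fold, 126 of 199 such hairpins were called over 10 simulated data sets, and 14 of 1116 unmoved ones.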

Results

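Mature microRNAs were counted in 3 EV and 3 KO libraries of a mouse epicardial cell line, to find which microRNAs differ when Hdac3, a histone deacetylase that acts in repressor complexes, is targeted. The series title places a microRNA pathway between epicardial Hdac3 and growth of the myocardium. The totals were 12806873, 11824881 and 12194683 counts in EV 1, EV 2 and EV 3, and 13412774, 12720548 and 12919981 in KO 1, KO 2 and KO 3. Small-RNA libraries do not measure the Hdac3 mRNA, so the knockout itself was not checked here. miR-21a-5p, an abundant microRNA of fibroblast-like cells, took 67.0% ± 3.63 of the counts in EV (SD, n = 3) and 68.2% ± 1.40 in KO (SD, n = 3). The other most abundant microRNAs were miR-143-3p, miR-148a-3p, let-7i-5p and miR-27b-3p, with log2 changes of 0.11 (SE 0.10), 0.08 (SE 0.10), -0.00 (SE 0.09) and 0.17 (SE 0.09). Neither these nor miR-21a-5p (log2 change 0.16, SE 0.18) was called by edgeR. In the fit without EV 3 and KO 2, chosen after the data were seen, miR-21a-5p was called, at 0.35 (SE 0.12, edgeR adjusted p = 0.0432).

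KO cells had more miR-322-5p, miR-503-5p and miR-34 family members than EV cells, and less miR-200a-3p, miR-200b-3p and miR-455-5p. Of 460 microRNAs tested, 35 were called, 23 higher and 12 lower in KO (edgeR quasi-likelihood, Benjamini-Hochberg). The 3 KO values lay entirely above or below the 3 EV values for each of these 35, and for 29.1% of all tested microRNAs, where chance gives 10%. Changes among the called microRNAs ran from 1.22-fold to 3.53-fold. The latter was a fall of miR-5128, a microRNA named here after its values were seen, which had a mean of only 0.741 CPM and kept its call in 9 of 17 other settings (adjusted p up to 0.143). For miR-5128 the authors' deposited table gives a log2 change of -1.24, against -1.82 (SE 0.47) by edgeR. The called pairs miR-24-2-5p with miR-3074-2-3p and miR-467a-5p with miR-467b-5p had near-equal counts, so 33 distinct signals were called. The count was 23, 16 and 59 without EV 1, EV 2 and EV 3, and 16, 15 and 19 without KO 1, KO 2 and KO 3. With library size alone as the scaling, which moved the median log2 change of all microRNAs from -0.01 to -0.16, 5 were called, 1 higher and 4 lower. Library sizes without miR-21a-5p moved that median to -0.11 and gave 18 higher and 25 lower.

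**Figure D1:**
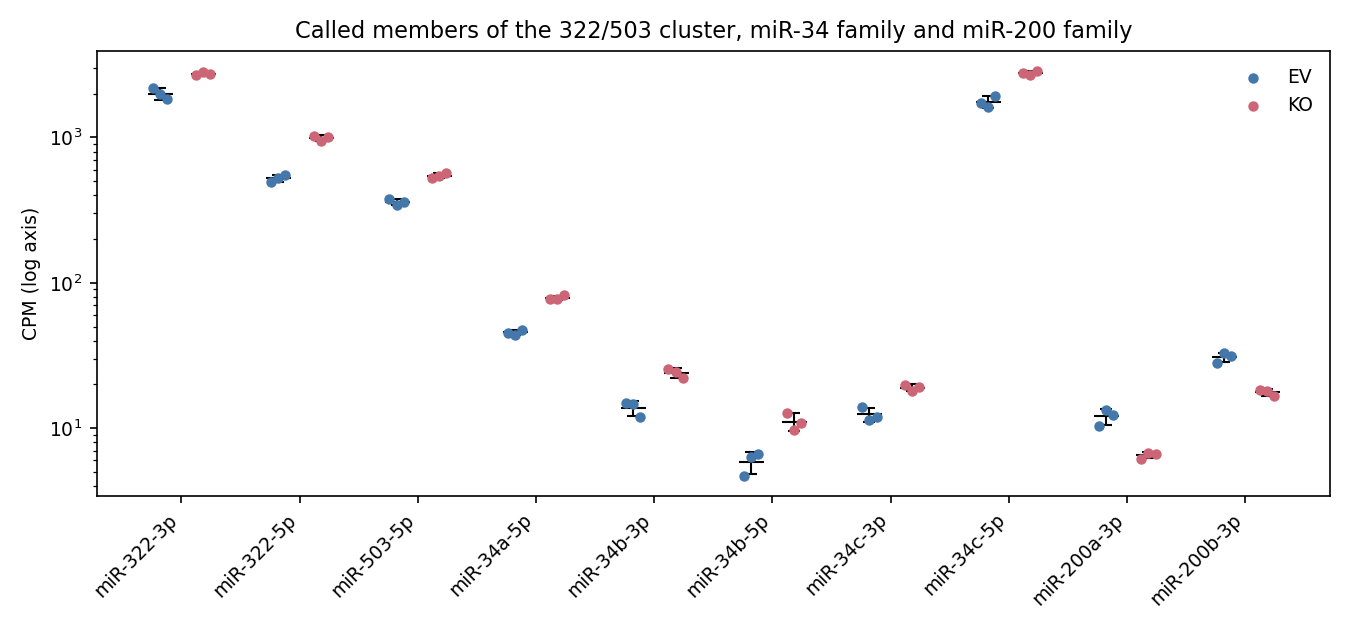
Normalized counts (CPM, log axis) of the called members of the miR-322/miR-503 cluster, the miR-34 family and the miR-200 family, with 1 point per library (3 EV, 3 KO) and lines at the mean ± SD. For each microRNA shown the KO points lie on 1 side of the EV points, as for miR-322-5p with a mean of 522 CPM in EV and 989 in KO.

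In the X-linked miR-322/miR-503 cluster, whose first hairpin yields a microRNA with the miR-15/16 seed, miR-322-5p, miR-503-5p and miR-322-3p rose in KO, and 9 of 12 tested members were not called. miR-322-5p rose from 522 ± 31.3 to 989 ± 44.98 CPM (SD, n = 3 each), a 1.89-fold change (log2 0.92, SE 0.07, edgeR Benjamini-Hochberg adjusted p = 1.06e-04). miR-503-5p rose from 358 ± 16.98 to 543.5 ± 21.3 CPM (log2 0.60, SE 0.07, edgeR adjusted p = 0.00186), and miR-322-3p from 2005 ± 184 to 2746 ± 67.3 CPM (log2 0.45, SE 0.08, edgeR adjusted p = 0.00992). The hairpins lie on the minus strand of chromosome X in GRCm38, Mir322 at 53054255 to 53054349 and Mir503 at 53053984 to 53054054, outside annotated host genes. Mir351 (53053255 to 53053353), Mir542 (53049403 to 53049487) and Mir450b (53047997 to 53048078) follow in the direction of transcription.

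Of the 12 tested members of the cluster, 3 rose, 5 adjusted over the list alone, and 9 were not called by edgeR. All 12 log2 changes were above 0 in the main fit. With library size alone miR-351-5p, miR-450a-5p, miR-450b-3p, miR-542-3p and miR-542-5p lay below 0, and with library sizes without miR-21a-5p miR-351-5p, miR-450a-5p and miR-542-5p. miR-351-5p also lay below 0 without EV 2, and miR-542-5p without the filter, without EV 3, without KO 1, with the surrogate variable and without EV 3 and KO 2. miR-351-5p, miR-450a-5p and miR-542-3p were as abundant as miR-503-5p (727, 943 and 1250 CPM on average), with log2 changes of 0.07 (95% interval -0.16 to 0.29), 0.05 (-0.11 to 0.21) and 0.10 (-0.11 to 0.30). The other members not called were miR-503-3p at 0.34 (SE 0.10), miR-450b-5p at 0.31 (SE 0.11), miR-351-3p at 0.48 (SE 0.20), miR-450a-1-3p at 0.20 (SE 0.19), miR-450b-3p at 0.14 (SE 0.13) and miR-542-5p at 0.03 (SE 0.23). The list stood above the other microRNAs at the preset correlation (camera, adjusted p = 3.41e-04), with camera adjusted p = 0.0774 with an estimated correlation. As the candidate already known for this study, the cluster was not an independent choice of list. Without EV 3, 5 members were called, and miR-322-3p was not called without EV 2 (edgeR adjusted p = 0.0907) or without KO 2 (edgeR adjusted p = 0.0559). With library size alone miR-322-5p was the only called member, at a log2 change of 0.77 (SE 0.10), with miR-503-5p at 0.44 (SE 0.14) and miR-322-3p at 0.28 (SE 0.16).

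**Figure D2:**
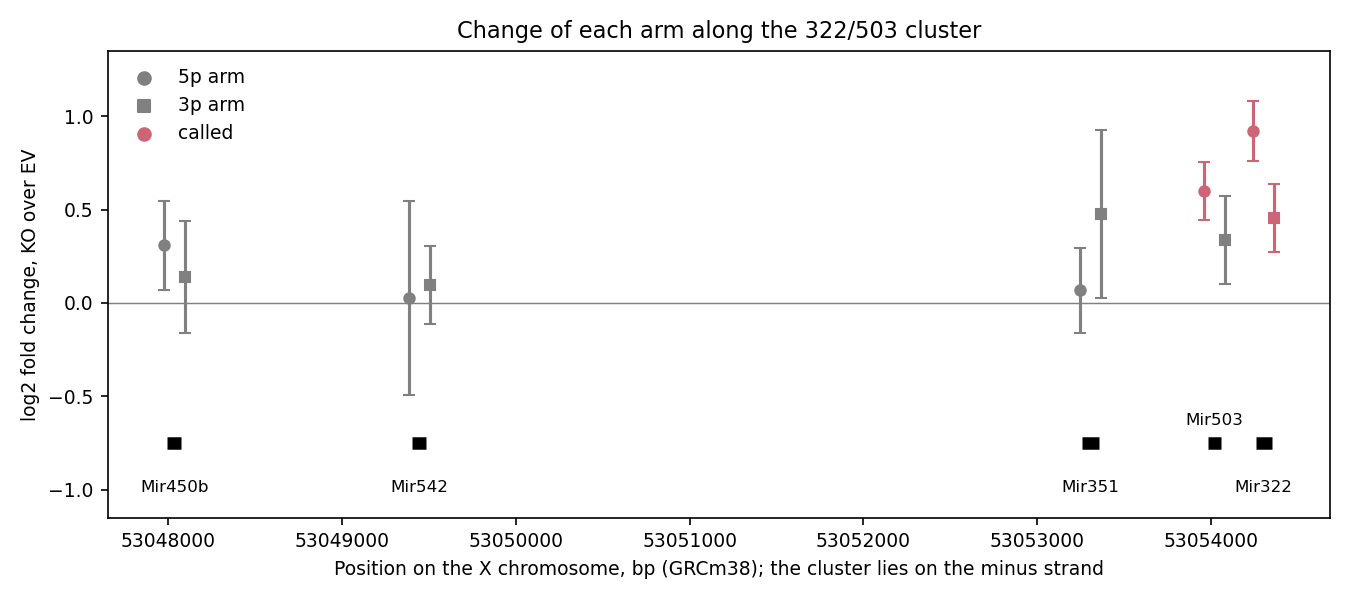
Log2 fold change of KO over EV (with 95% intervals) for each arm of 5 hairpins of the miR-322/miR-503 cluster, plotted beside its hairpin on chromosome X (GRCm38, positions in bp, black boxes are hairpins, circles 5p arms, squares 3p arms, red called). The called arms belong to Mir322 and Mir503, at 0.92, 0.45 and 0.60.

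All tested members of the miR-34/miR-449 list rose in KO, and all are arms of miR-34, known as a target of p53, since no miR-449 passed the filter. The 5 tested members were called, and 5 adjusted over the list alone (edgeR). miR-34c-5p, the most abundant, rose from 1764 ± 162 to 2771 ± 89.1 CPM (SD, n = 3 each), with a log2 change of 0.65 (SE 0.08, edgeR adjusted p = 0.00220). miR-34a-5p rose from 45.6 ± 1.69 to 78.9 ± 2.67 CPM (log2 0.79, SE 0.10), while miR-34b-5p, miR-34b-3p and miR-34c-3p rose by 0.92 (SE 0.18), 0.80 (SE 0.15) and 0.61 (SE 0.14) on the log2 scale. Mir34b and Mir34c share a cluster on chromosome 9 at 51103034 to 51103645, and Mir34a lies apart on chromosome 4 at 150068454 to 150068555. The list median was 0.79 (camera, adjusted p = 1.80e-06), with camera adjusted p = 0.0518 with an estimated correlation. The 5 members share hairpins and in part a cluster, so they are not independent. Only 2 members were called without EV 2 or without KO 1, 4 without KO 2 or without KO 3, and 0 with library size alone, where the median was 0.63 and miR-34c-5p stood at 0.50 (SE 0.11).

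In the miR-200 family, known to hold cells in an epithelial state by repressing Zeb1 and Zeb2, miR-200a-3p and miR-200b-3p were lower in KO, at low levels. miR-200b-3p fell from 30.7 ± 2.25 to 17.7 ± 0.898 CPM (SD, n = 3 each), with a log2 change of -0.80 (SE 0.13, edgeR adjusted p = 0.00777). miR-200a-3p fell from 12.03 ± 1.496 to 6.53 ± 0.323 CPM (log2 change -0.88, SE 0.15, edgeR adjusted p = 0.00898). Both hairpins lie in an intron of Ttll10 on chromosome 4 (Mir200a at 156054896 to 156054985, Mir200b at 156055681 to 156055750). Of the 5 tested members 2 fell, 4 adjusted over the list alone, and miR-200a-5p, miR-429-3p and miR-200c-3p, at -0.70 (SE 0.26), -0.67 (SE 0.27) and -0.33 (SE 0.39), were not called (edgeR). The list median was -0.70 (camera, adjusted p = 0.00121), with camera adjusted p = 0.196 with an estimated correlation.

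The imprinted Dlk1-Dio3 cluster and the miR-181 family leaned lower in KO. Of the 77 tested Dlk1-Dio3 microRNAs, 69 had log2 changes below 0, 2 fell and 1 fell adjusted over the list alone (edgeR). miR-409-3p fell from 293.8 ± 34.99 to 204.4 ± 15.98 CPM (SD, n = 3 each; log2 change -0.52, SE 0.10, edgeR adjusted p = 0.0130), and miR-370-3p from 142.8 ± 23.6 to 93.7 ± 14.0 CPM (log2 change -0.61, SE 0.14, edgeR adjusted p = 0.0290). Both are intronic on chromosome 12, Mir409 in Mirg at 109743158 to 109743236 and Mir370 in Rian at 109618258 to 109618336. The Dlk1-Dio3 median was -0.24 (camera, adjusted p = 6.57e-10), and this list alone stayed under the threshold with an estimated correlation (camera adjusted p = 0.0425). The Dlk1-Dio3 members share 1 imprinted cluster and in part hairpins, so the 69 are not independent. Of the 9 tested miR-181 microRNAs, all with log2 changes below 0, miR-181b-5p and miR-181a-2-3p fell, at -0.41 (SE 0.09) and -0.63 (SE 0.15), and the other 7 were not called by edgeR (2 fell adjusted over the list alone). The miR-181 list had camera adjusted p = 0.00121, and camera adjusted p = 0.0910 with an estimated correlation. For Dlk1-Dio3, 7 were called without EV 3, 0 without KO 1, 1 without each of EV 1, EV 2 and KO 2, 9 with DESeq2, 4 with limma-voom, 8 without the filter and 10 with library sizes without miR-21a-5p. Library size alone gave 0 calls, although the falls were larger, with larger errors, at -0.69 (SE 0.17) for miR-409-3p and -0.79 (SE 0.21) for miR-370-3p. For miR-181, 1 was called without EV 2, 0 without EV 1, KO 1, KO 2 or KO 3, and 3 with library sizes without miR-21a-5p. No miR-181 member was called with library size alone, at -0.57 (SE 0.13) for miR-181b-5p and -0.80 (SE 0.23) for miR-181a-2-3p.

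Members of the miR-23/27/24 clusters and of the Sfmbt2 intron cluster rose in KO. miR-23a-3p rose from 226 ± 2.15 to 316 ± 13.7 CPM (SD, n = 3 each; log2 0.49, SE 0.07, edgeR adjusted p = 0.00346), and miR-24-2-5p by 0.49 (SE 0.09). The latter had near-equal counts to the overlapping antisense name miR-3074-2-3p, which points to shared reads, and is uncertain for that reason. Of the 10 tested miR-23/27/24 members, with a median of 0.24, 2 rose, 4 adjusted over the list alone, and 8 were not called (edgeR). That list had camera adjusted p = 4.45e-04, and camera adjusted p = 0.159 with an estimated correlation. In the Sfmbt2 cluster 3 of 24 tested members rose, 4 adjusted over the list alone, namely miR-669a-3p at 0.73 (SE 0.15) and the near-identical miR-467a-5p and miR-467b-5p, both at 0.29 (SE 0.08, edgeR adjusted p = 0.0499). Mature miR-669a-3p maps to 12 hairpins and miR-467a-5p to 10, so counts for single copies are uncertain. The Sfmbt2 list had camera adjusted p = 0.00252, and camera adjusted p = 0.190 with an estimated correlation. With edgeR, 0 Sfmbt2 members were called without EV 2, KO 1, KO 2 or KO 3, and 1 without EV 1. Neither list had a called member with library size alone, with miR-23a-3p at 0.33 (SE 0.12), miR-669a-3p at 0.56 (SE 0.20) and miR-467a-5p and miR-467b-5p at 0.14 (SE 0.12). miR-467a-5p kept its call in only 9 of 20 other settings (adjusted p up to 0.519), and miR-669a-3p in 13 of 19, not with DESeq2 (DESeq2 adjusted p = 0.113). miR-24-2-5p was not called without EV 2 (edgeR adjusted p = 0.0910) or KO 2 (edgeR adjusted p = 0.0582), which left 1 called miR-23/27/24 member.

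miR-217-5p, a pancreas microRNA in the neural, liver and pancreas list, rose from 5.45 ± 1.20 to 11.3 ± 1.23 CPM (SD, n = 3 each), a 2.08-fold change (log2 1.05, SE 0.19, edgeR adjusted p = 0.00992). It was the only called member of 7 tested, against 2 adjusted over the list alone (camera for this list, adjusted p = 0.105). Without EV 3, 2 members of that list were called. miR-532-5p, in an intron of Clcn5 on chromosome X (7248402 to 7248497), rose from 800 ± 68.4 to 1204 ± 49.6 CPM (log2 0.59, SE 0.08, edgeR adjusted p = 0.00245). miR-101a-3p rose from 486.5 ± 42.7 to 723 ± 52.9 CPM (log2 0.57, SE 0.08, edgeR adjusted p = 0.00442). These rises were not called with library size alone, at 0.89 (SE 0.22) for miR-217-5p, 0.43 (SE 0.14) for miR-532-5p and 0.41 (SE 0.12) for miR-101a-3p. miR-455-5p, in an intron of the collagen gene Col27a1 on chromosome 4 (63256851 to 63256932), fell from 130 ± 16.2 to 83.9 ± 1.33 CPM (log2 change -0.63, SE 0.10, edgeR adjusted p = 0.00777). miR-1983, miR-340-5p and miR-708-5p fell by 0.63 (SE 0.14), 0.59 (SE 0.13) and 0.58 (SE 0.14) on the log2 scale, and with library size alone by 0.78 (SE 0.18), 0.74 (SE 0.15) and 0.72 (SE 0.17), where they were not called. In the replicate-omission fits miR-340-5p was called only without EV 1 or EV 3, miR-1983 only without EV 3, and miR-708-5p in 0 of them, with edgeR adjusted p up to 0.142.

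The miR-15/16 seed list passed (camera adjusted p = 0.0105), and had camera adjusted p = 0.196 with an estimated correlation. Of its 6 tested members miR-322-5p alone was called by edgeR, against 2 adjusted over the list alone, and without it the other 5 had a median of 0.27 (camera, unadjusted p = 0.0757). Without EV 3, 3 members were called. The miR-221/miR-222 list passed narrowly (camera adjusted p = 0.0492), and had camera adjusted p = 0.335 with an estimated correlation. None of its 4 members was called by edgeR, 1 was adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 each. miR-221-3p, the most abundant, had a log2 change of 0.38 (SE 0.11) and was called without EV 3 (edgeR adjusted p = 0.0168).

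**Figure D3:**
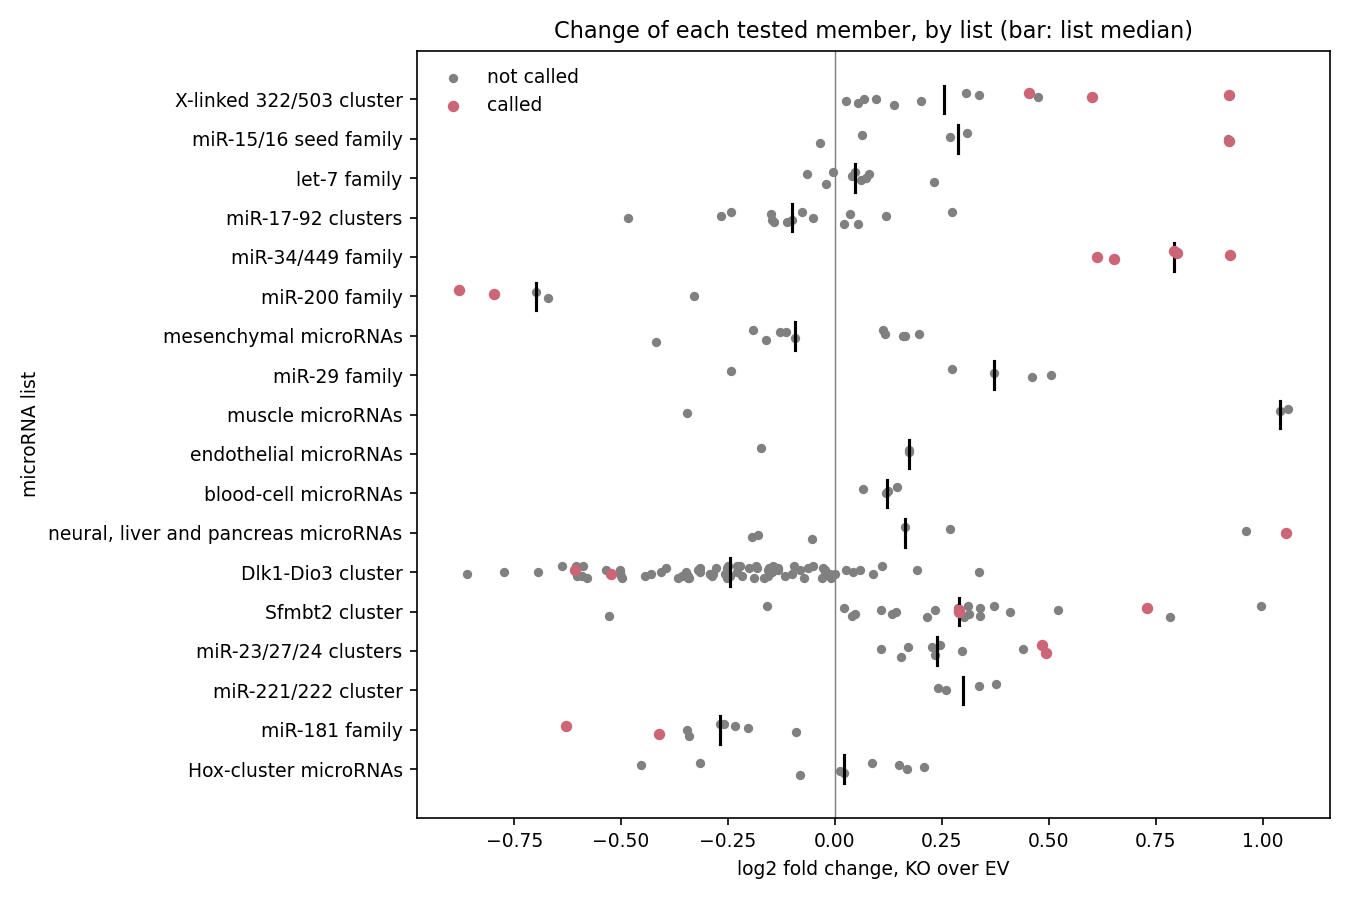
Log2 fold change of KO over EV for each tested member of the 18 lists with at least 3 tested members, 1 point per microRNA, red where called, with a bar at the list median. The miR-34/miR-449 points lie between 0.61 and 0.92, and the miR-200 points between -0.88 and -0.33.

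In the main fit edgeR called no member of the let-7 (9 tested), miR-17-92 (15), mesenchymal (11), miR-29 (5), muscle (3), endothelial (3), blood-cell (4), Hox-cluster (9) or Igf2/H19 (1) lists, and neither DESeq2 with its default trend nor limma-voom called any. With a local trend DESeq2 called 1 let-7, 1 miR-29, 1 muscle and 1 Hox-cluster member. At an unadjusted p under 0.05 there were 1, 0, 0, 1, 3, 0, 0, 1 and 0 members in that order. Adjusted over the list alone, 1 miR-29 and 3 muscle microRNAs passed and 0 in the other lists. Of the muscle ones 2 were higher and 1, miR-206-3p, lower. The higher ones, miR-1a-3p and miR-1b-5p, had near-equal counts of at most 2.35 CPM, so they count as 1 signal, here and without EV 3. Their camera adjusted p were 0.533, 0.419, 0.830, 0.105, 0.462, 0.987, 0.987 and 0.970, with Igf2/H19 too small to test. The most abundant members were let-7i-5p, miR-21a-5p, miR-25-3p at 0.12 (SE 0.07), miR-29a-3p at 0.27 (SE 0.08), miR-206-3p at -0.35 (SE 0.13), miR-126a-3p at -0.17 (SE 0.12), miR-451a at 0.14 (SE 1.64), miR-10a-5p at 0.15 (SE 0.12) and miR-483-3p at -0.85 (SE 0.64). Without EV 3, edgeR called 1 miR-29, 2 muscle and 1 Hox-cluster member, without the filter 1 mesenchymal and 1 Hox-cluster member, and 1 miR-29 member with the 10 CPM filter or without the 5 most abundant microRNAs. Without EV 3 and KO 2 members of 7 of these lists were called. The endothelial and blood-cell medians were above 0 (0.17 and 0.12) where camera gave a downward direction, and the Hox-cluster mean was -0.02 against a median of 0.02. Pluripotency microRNAs were not tested, as none of the 12 in the table passed the filter, and none had more than 14 reads in a library.

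Among markers of other cell types, miR-451a of red blood cells was high in 1 library of each group. It stood at 0.892, 2.45 and 54.7 CPM in EV 1, EV 2 and EV 3, and at 0.243, 62.7 and 0.573 CPM in KO 1, KO 2 and KO 3. The neural microRNA miR-9-5p was also highest in these libraries, at 51.4 CPM in EV 3 and 57.1 in KO 2, against 11.3 to 32.6 elsewhere. The endothelial miR-126a-3p stayed between 31.7 and 39.4 CPM in all 6. The first principal component, 49.6% of the variance, set EV 3 and KO 2 apart from the others, and the second, 28.3%, separated KO from EV. The components were computed on unscaled log CPM of 303 microRNAs that include miR-451a. The first may therefore largely repeat the miR-451a values, and its share is not evidence of a difference across all microRNAs. Without EV 3 and KO 2, 88 microRNAs were called, 54 higher and 34 lower, including 34 of the 35. That fit drops 1 library of each group because these stood apart, which by itself can lower the spread within groups. Its further calls are uncertain for that reason. In that fit 5 members of the miR-322/miR-503 cluster, 5 of miR-34/miR-449, 2 of miR-200, 13 of Dlk1-Dio3, 3 of miR-181, 2 of miR-23/27/24 and 4 of Sfmbt2 were called. So were 3 of miR-29, 3 of miR-221/miR-222, 3 Hox-cluster, 2 mesenchymal, 2 muscle, 2 miR-15/16 seed, 1 let-7, 1 miR-17-92, 1 blood-cell and 1 member of the neural, liver and pancreas list.

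**Figure D4:**
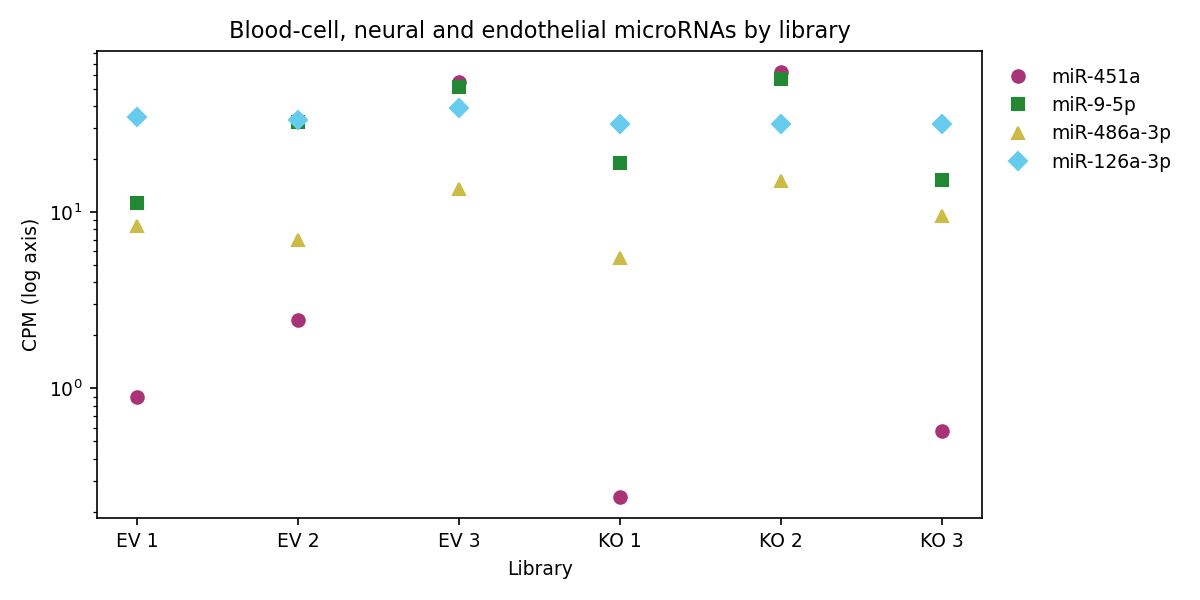
Normalized counts (CPM, log axis) of microRNAs of red blood cells (miR-451a and miR-486a-3p), neurons (miR-9-5p) and endothelium (miR-126a-3p) in each of the 6 libraries, 1 point per library. miR-451a reaches 54.7 CPM in EV 3 and 62.7 in KO 2 and is at most 2.45 in the others.

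The authors' deposited table lists 78 microRNAs, 42 higher and 36 lower in KO. All 35 microRNAs called by edgeR are in the authors' deposited table with the same sign. Both rest on the counts of the same 6 libraries, and that table lists more microRNAs. The overlaps given here are therefore not independent support. For miR-322-5p the authors' deposited table gives a log2 change of 0.90, and for miR-200b-3p -0.80. The other 43 microRNAs of the authors' deposited table had the same sign by edgeR but were not called, with a median edgeR adjusted p of 0.0921. Without EV 1, EV 2, KO 1, KO 2 and KO 3 the overlap was 23, 16, 16, 15 and 19, which is every microRNA called in each of those fits.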

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

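The surrogate variable, the fit without EV 3 and KO 2, DESeq2 with a local trend, 1 member per shared-read pair and library sizes without miR-21a-5p were chosen after the data were seen. None of the 25 named microRNAs that were called changed direction in any setting. miR-322-5p, miR-200a-3p, miR-200b-3p and miR-455-5p were called in each of 20 settings, which leave out the 2-fold minimum. Library size alone gave 5 calls (1 higher, 4 lower), 1 in the miR-322/miR-503 cluster, and 5 shared with the authors' table, and a minimum of 2-fold gave 2 (1 higher, 1 lower), 0 in the cluster and 2 shared. Without the filter there were 56 calls, 28 of them lower. DESeq2 called 21 lower, the surrogate variable 19 and library sizes without miR-21a-5p 25. The DESeq2 local trend called 69 (38 higher, 31 lower), 5 in the cluster and 62 shared with the authors. Without EV 3 and KO 2 there were 88 (54 higher, 34 lower), 5 in the cluster and 54 shared. With single libraries left out the calls ran from 15 to 59 (higher 10 to 40, lower 3 to 19), the cluster from 2 to 5 and the overlap with the authors from 15 to 49, the highest of each without EV 3. Of 9 lists, 1 kept its call with an estimated correlation. The estimates were -0.065 for miR-322/miR-503, -0.039 for miR-34/miR-449, -0.075 for miR-181 and 0.0094 for Dlk1-Dio3, against the preset 0.01. A higher correlation therefore did not cost the first 3 of these their calls. For Dlk1-Dio3 the estimate lay just under the preset value, yet camera adjusted p rose from 6.57e-10 to 0.0425. The 2 settings thus differ in more than the correlation. The p-values given with an estimated correlation therefore do not measure the effect of correlation alone. For the other lists called at the preset value the estimates lay between 0.0488 and 0.426. Apart from library size alone, the cause of these differences was not tested.

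Pairing of the libraries by replicate number was not seen, but the check cannot exclude it. Deviations of same-numbered EV and KO libraries correlated at 0.370, -0.345 and -0.428 over 303 microRNAs, and 0 of 6 libraries correlated best with their own number. Between differently numbered libraries the correlations ran from -0.582 to 0.637, the latter for EV 3 with KO 2. The 303 microRNAs include miR-451a, high in EV 3 and KO 2, which may largely set these values. With the replicate block 34 were called (22 higher, 12 lower), 29 of them among the 35, 3 in the cluster, 32 shared with the authors, and 8 lists.

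MicroRNAs that were not called turned direction in some settings. With library size alone log2 changes were -0.044 for miR-143-3p, -0.074 for miR-148a-3p, -0.045 for miR-25-3p, -0.093 for miR-351-5p, -0.11 for miR-450a-5p, -0.0084 for miR-450b-3p, -0.046 for miR-542-3p and -0.16 for miR-542-5p. With library sizes without miR-21a-5p they were -0.020 for miR-148a-3p, -0.030 for miR-351-5p, -0.046 for miR-450a-5p and -0.080 for miR-542-5p. let-7i-5p was at 0.0070 with the 10 CPM filter, 0.011 with the surrogate variable and 0.038 without EV 3 and KO 2. miR-542-5p was at -0.0038 without the filter, -0.041 with the surrogate variable and -0.094 without EV 3 and KO 2. miR-451a was at -0.92 with limma-voom, -1.01 with the replicate block, -0.15 with the surrogate variable and -1.96 without EV 3 and KO 2, where alone it was called (edgeR adjusted p = 0.0223, against up to 0.983 over its settings). With single libraries left out, log2 changes ran from -0.062 to 0.042 for let-7i-5p, from -0.064 to 0.13 for miR-351-5p, from -0.17 to 0.24 for miR-542-5p and from -5.51 to 3.69 for miR-451a.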

Other observations

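The tests of the miR-322/miR-503 cluster and of miR-451a, and the choice of the Clcn5 microRNAs, were made after the results were seen, while those of the sample splits, the share of miR-21a-5p and the hairpin arms were set before.

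Of 7 tested microRNAs from Mir500 to Mir532, in the introns of Clcn5 on the minus strand of chromosome X (7237683 to 7248497), 3 were called higher in KO. All 7 log2 changes were above 0, with a median of 0.59, but the group is not among the fixed lists and was not tested as a set. The called ones were miR-532-5p, miR-362-3p and miR-500-3p, the last pair at 0.75 (SE 0.15) and 0.62 (SE 0.15) by edgeR, but miR-500-3p kept its call in only 9 of 19 other settings (adjusted p up to 0.183) and miR-362-3p in 15 (up to 0.150), and miR-532-5p in 19 of 20. Of 32 X-linked microRNAs with 1 locus, 6 rose and 0 fell, with a median of 0.28, against -0.05 for 356 autosomal ones. All 6 lie in the Clcn5 introns or the miR-322/miR-503 cluster, and 0 of the 15 outside both were called.

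The 5p and 3p arms of 1 hairpin moved together. Over 266 arms of hairpins with both arms tested, the log2 changes of the arms correlated at r = 0.617 and rho = 0.647 across hairpins, which are not independent replicates. For 0 of the 9 other splits of the 6 libraries was r as high, the highest being 0.354, although 10 splits cannot give a share under 0.05. This is what a change in the supply of hairpins rather than of single arms would give, and it remains a hypothesis. By diffSplice 0 arm differences were called, 6 had an unadjusted p under 0.05, and the smallest p was for miR-322-5p, which rose by 0.47 more than miR-322-3p on the log2 scale (limma diffSplice, adjusted p = 0.126).

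The changes within the miR-322/miR-503 cluster were uneven, with 3 of 12 members called and miR-322-5p ahead of the others. One equal change of the 10 members placed at 1 locus was excluded by the within-cluster test (limma diffSplice, adjusted p = 9.10e-05, the only 1 of 25 clusters called). miR-450a-5p and miR-450a-1-3p were not in that test. Among its member tests only miR-322-5p was called (limma diffSplice, adjusted p = 6.83e-05), not miR-503-5p (0.462) or miR-322-3p (0.907). Low counts were excluded for 3 abundant members, miR-351-5p, miR-450a-5p and miR-542-3p, whose upper bounds lay under the lower bound of miR-503-5p. For the 6 less abundant members not called low counts stay open, since the intervals of 5 overlapped that of miR-503-5p and that of miR-450b-3p ended at 0.440, just under its lower bound of 0.445. A falling-off along the direction of transcription cannot be told apart from other orders, since 6 hairpins gave rho = -0.77 with an exact two-sided permutation p = 0.103. A gain of X chromosome dosage alone would raise neighbouring members alike, so it cannot give the unevenness. The upper bounds of miR-351-5p, miR-450a-5p and miR-542-3p, at 0.29, 0.21 and 0.30, limit such a gain here. Whether a gain within these bounds adds to the called rises stays open. The 22 X-linked microRNAs outside the cluster had a median of 0.25 (95% bootstrap interval 0.04 to 0.49). Over the 15 outside the Clcn5 cluster as well it was 0.08 (-0.02 to 0.26), the form in which the test was first run. The bootstrap drew microRNAs as if independent, although some share a hairpin or cluster. Hdac3 loss itself, the difference the design names, stays open and was not tested further.

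miR-451a was high in EV 3 and KO 2, 1 library of each group, and a part of the knockout in this was not tested. RNA of another tissue may have entered these libraries, and the data leave this open. Of 8 other tested microRNAs of the blood-cell and the neural, liver and pancreas lists, 2, miR-486a-3p and miR-9-5p, had their 2 highest libraries there, where chance gives 0.533 (one-sided exact binomial p = 0.0951). This counts the miR-486a arms once, because their counts lay within 10% of each other, a choice made after a first count with the arms apart had given 3 of 9 (one-sided exact binomial p = 0.0183). Below the filter, neural miR-124-3p had 8 reads in EV 3 and 9 in KO 2 against at most 2 elsewhere, and miR-9-3p 11 and 10 against 2 to 8. Other listed microRNAs below the filter went against this, as miR-124-5p had 0 and 5 reads there against 3 to 8 elsewhere, miR-150-5p was highest in EV 2 with 10, miR-144-3p, whose hairpin lies beside Mir451a, had 0 in both, and miR-142a-3p and miR-223-3p of white blood cells had at most 3 and 2 reads in any library.

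Fewer microRNAs were called with library size alone, 5 against 35. The share of miR-21a-5p alone could account for this, as taking it out of the library sizes with no other factor gave 43 calls, of which 30 were among the 35. That scaling still left the median log2 change at -0.11, against -0.16 with library size alone and -0.01 with TMM, so it does not account for the whole shift.

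Among the 10 splits of the 6 libraries into 3 and 3, 1 split, that of KO against EV, gave 35 or more calls, and the highest of the others gave 4. The splits are too few for a share under 0.05.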
